A study of Homo sapiens with 6 samples.

How the data were processed

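Total RNA was sequenced from MB157, an established human triple-negative breast cancer cell line that carried the Cas9 nuclease according to the sample titles. Per the labels, cells received either a control sgRNA or an sgRNA against SOX9 for 4 days and were sorted by flow cytometry for the top 50% of sgRNA-expressing cells. RNA was isolated on RNeasy columns and made into libraries with a SMARTer stranded Pico Input kit, per the labels' protocols. This kit keeps the strand of the RNA. Each group held 3 libraries, 6 in all, and the labels call the replicates technical. P-values therefore measure the spread between these libraries and not the spread between independent experiments.

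The values used are counts of reads per gene, deposited by the authors as whole numbers without normalization, 1 table per library. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a and counted with featureCounts of Subread 1.6.2 on GRCh37 (hg19). Per the file headers, featureCounts 1.6.2 counted fragments over exons of Ensembl GRCh37 release 75 genes, with strand setting 1 and with fragments allowed to count for every gene they overlap. The headers name no option for multi-mapped reads. The annotation named there had no ribosomal RNA genes and no mitochondrial chromosome, and the tables held 0 mitochondrial genes. Reads of genes with near-identical copies, such as ribosomal protein genes with pseudogenes, HLA genes and HSPA1A, could have been lost or split, so their values are uncertain. The strand setting decides which of a pair of overlapping genes receives a read, and the distribution of counts over such pairs is given with the results.

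Each table held 57209 gene identifiers. Gene symbols came from a table of identifiers and symbols, and biotypes from GENCODE release 29, which is on another build and was used for no coordinates. Both were found for 51789 identifiers, of which 19250 are protein-coding. All coordinates are those of the deposited tables, on GRCh37. Exons of 11223 genes overlapped an exon of a gene on the other strand (bedtools 2.31.1).

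Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr at its defaults, libraries were scaled by TMM factors, and the robust quasi-likelihood fit and test compared SOX9 sgRNA with control sgRNA. No replicate block was used, since the labels do not say that a number is shared between groups. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM, the count of a gene relative to the library's total over tested genes, was scaled by the TMM factors, and CPM values are means with SD. Raw CPM, where named, is relative to the library's total over all genes, without factors. The alternative with library totals also used totals over tested genes. A log2 fold change is SOX9 sgRNA over control, with a prior count of 2 in the averaged log2 CPM, and is given with its standard error (SE).

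A total of 30 gene lists, with 844 entries of which 807 matched an identifier, were fixed before the data were examined, as were the tests and the rule for naming genes. The lists with at least 5 tested genes, 23 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The same test with an estimated correlation and fry, a rotation test, were alternatives. The named genes were SOX9, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among genes past the threshold whose average log2 CPM was at least 2 and whose groups did not overlap in any library, and up to 4 members of each list with the smallest adjusted p. Genes named outside this rule are said to be so. A few genes that the rules name are not reported here.

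After the counts had been seen, a further reading was added. Where the exons of a tested gene overlapped those of exactly 1 gene on the other strand, and that gene was protein-coding, the tested gene's count was also listed beside the gene on the other strand. These counts are called opposite counts here. There were 2672 of them, with the largest overlap kept where several genes qualified. The 12 largest rises and falls among opposite counts past the threshold, with an average log2 CPM of at least 6 and groups that did not overlap, are named. All results on opposite counts were chosen after seeing the data.

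The procedure was tested on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed by known folds. The changed genes were drawn only from genes with an average log2 CPM above 4. Recovery of genes with fewer counts was not measured. Of 50 genes changed at each size, the fit found 32% at 1.5-fold, 54% at 2-fold, 80% at 3-fold and 88% at 4-fold, all in the right direction, and called 5 of the 7247 unchanged genes that passed the filter. Of the 200 changed genes 188 passed it, and the others counted as not found. Depth was low: totals ran from 776125 to 1018854 counts per library, so that changes below 2-fold were often out of reach. The libraries carried no molecular identifiers that the deposited counts use, so counting intervals cover counting error only.

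Alternatives planned before the data were examined were median-of-ratios and upper-quartile factors, library totals without factors, no filter and a stricter filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, a test against 1.5-fold (glmTreat), protein-coding genes only, and leaving out each library. Added after seeing the data were the opposite counts, an overlap of at least 100 bp for them, genes without an exon on the other strand only, lists read on opposite counts, and counts after subtracting a diffuse background estimated from olfactory receptor genes. Checks of replicates, strands and detection used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.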

Results

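The data were gene counts from 6 RNA-seq libraries of MB157 cells, 3 with a control sgRNA and 3 with an sgRNA against SOX9, a transcription factor of the SRY-related HMG-box family. The comparison was made to find genes that depend on SOX9 in triple-negative breast cancer, a subtype without hormone receptors or HER2 amplification. Control libraries 1 to 3 held 841592, 881655 and 777960 counts, and SOX9 sgRNA libraries 1 to 3 held 829738, 776125 and 1018854. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 2.00 and 2.61, against 5.36 to 6.92 between groups. SOX9 sgRNA libraries detected more genes, from 20207 to 21082, than control libraries, with 18326 to 18818.

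Counts were highest on genes that lie opposite abundant genes. GAPDH, a glycolytic enzyme gene, had between 66 and 126 raw counts per library, while ENSG00000269968, which overlaps it on the other strand, had 7249 to 11002. FTH1, which encodes ferritin heavy chain, had 216 to 344 and BEST1 opposite it 8823 to 13164. RPS23, a ribosomal protein gene, had 5 to 22 and ATG10 opposite it 7005 to 9802. Of the 100 genes with the highest mean CPM, 92 had an exon on the other strand and 1 was a ribosomal protein gene. In every library about 81% of counts lay in genes with an exon on the other strand (80.9% to 81.5%). Counts were kept apart by strand, and those of GAPDH, FTH1 and RPS23 were far below those of the genes opposite them. It is open whether a count holds transcripts of the gene it is named for or of the gene on the other strand. For many named genes the gene on the other strand is therefore given.

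The targeted gene, SOX9 (ENSG00000125398, chromosome 17, 70117161 to 70122561, plus strand, GRCh37), showed no detectable change in its counts. Control libraries 1 to 3 held 38, 52 and 44 counts and SOX9 sgRNA libraries 37, 39 and 60, or 60.01 ± 8.15 against 51.2 ± 6.94 CPM (SD, n = 3 each). The log2 fold change was -0.22 (SE 0.26, edgeR adjusted p = 0.70), a difference within the spread of the replicates. No annotated exon lies opposite SOX9. With counts elsewhere lying mainly opposite abundant genes, whether these counts measure SOX9 mRNA is open. A guide that shifts the reading frame also need not lower the transcript, so these counts neither check nor contradict the labels. The series describes the cells as stably expressing SOX9 where the titles name Cas9, and whether a transgene added to these counts is not given in the sources used here.

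With the SOX9 sgRNA, counts fell for S100A13, for VIM and GABRP with the genes opposite them, and for genes of the cholesterol synthesis list, and rose for ZBTB7C, NEK7 and RMDN2 and opposite CYP1B1 and HLA-B. S100A13, which encodes a small calcium-binding protein, fell from 1904 ± 174 to 224 ± 14.5 CPM, a log2 fold change of -3.09 (SE 0.090, edgeR adjusted p = 3.58e-41), and lay opposite S100A1 over 239 bp of exon. Its span also overlaps that of ENSG00000272030 on the same strand, and a shared fragment could count for both. SCD, the desaturase that makes oleic acid, fell from 94.8 ± 14.3 to 18.3 ± 1.33 CPM (log2 fold change -2.37, SE 0.28, edgeR adjusted p = 1.12e-09) and had no exon opposite. Whether these counts measure SCD mRNA is open, as for SOX9. Of 7959 genes tested, 238 were higher and 479 lower. At 2-fold or more, 111 were higher and 137 lower. The balance of directions depended on scaling: with library totals in place of TMM factors, 625 genes were higher and 249 lower, since that scaling moved the median log2 fold change of all genes from 0.01 to 0.19. The 2 groups did not overlap for 24.4% of tested genes, where chance gives 10%.

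**Figure D1:**
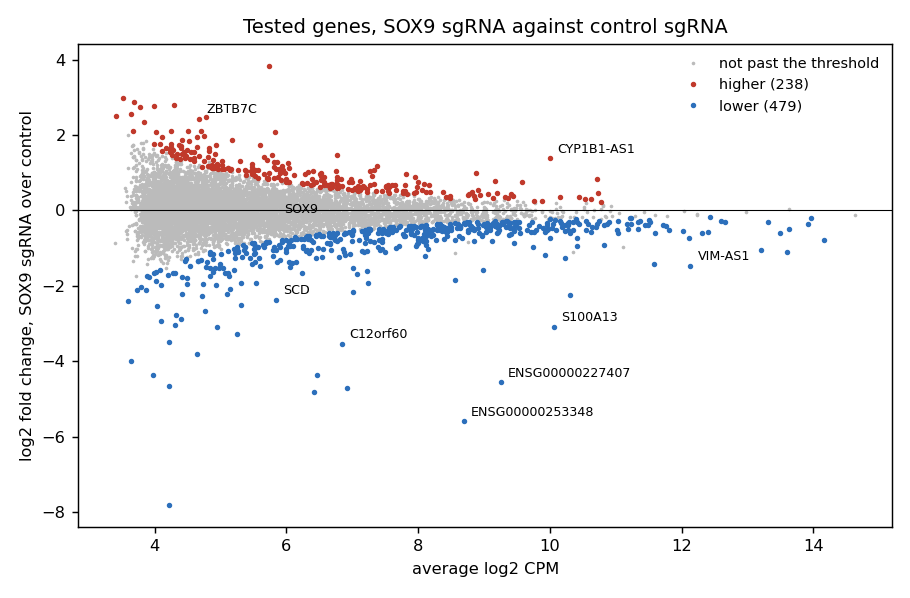
Average log2 CPM (horizontal) against the log2 fold change of SOX9 sgRNA over control (vertical) for the 7959 tested genes, with 238 higher genes in red, 479 lower genes in blue and genes not past the threshold in grey. SOX9 lies near 0 at -0.22, while S100A13 and VIM-AS1 lie far below 0 at high counts, and the lowest point is a fitted value for a gene with 0 counts in all SOX9 sgRNA libraries.

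The 12 largest falls among protein-coding genes included PCARE, which encodes an actin regulator of photoreceptor cilia, with 73 control counts against 3 over the groups, a ratio of 25.5 (exact 95% counting interval 8.40 to 127). ALKBH8, a tRNA methyltransferase gene, had 60 against 3, a ratio of 21.0 (6.85 to 105). Both rested on few SOX9 sgRNA counts. For PCARE the ratio was 54.0 without SOX9 sgRNA library 2 and 15.6 without SOX9 sgRNA library 3. For ALKBH8 all 3 counts came from SOX9 sgRNA library 1, without which 60 stood against 0, a ratio of at least 11.3 by the lower 95% bound, and the ratio was 12.8 without SOX9 sgRNA library 3. The log2 fold change was -3.81 for CEP20, -3.54 for C12orf60, -3.28 for DLEU7, -2.93 for GABRP, -2.66 for EPHX4, -2.51 for TBPL1, -2.41 for AMER1 and -2.23 for AIF1L, all past the threshold with groups that did not overlap. Several lay opposite other genes: PCARE opposite TOGARAM2, C12orf60 opposite MGP, TBPL1 opposite SLC2A12 and GABRP opposite ENSG00000253348. ALKBH8, CEP20, DLEU7, EPHX4, AMER1 and AIF1L had no exon opposite, and whether their counts measure the mRNAs of these genes is open. Without SOX9 sgRNA library 1 the value of DLEU7 was -3.90. Among these 12 falls, 11 stayed past the threshold when any single library was left out. AMER1, an inhibitor of Wnt signalling with 38 counts against 8, did so in 1 of 6 such fits, with values from -3.29, without SOX9 sgRNA library 2, to -2.05, and was lost without any control library and without SOX9 sgRNA library 1 or 3.

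The 12 largest rises rested on fewer counts. The log2 fold change was 2.98 for ZNF81, 2.89 for KCND2, a voltage-gated potassium channel gene, 2.44 for ZBTB7C, 2.36 for TNFRSF17, 2.12 for RMDN2, 2.10 for TINF2, a telomere shelterin gene, 2.09 for SLPI, a secreted protease inhibitor gene, 1.98 for NEK7, 1.95 for ZFP41, 1.85 for CDR1, 1.78 for RRAGC and 1.74 for MFSD13A. ZBTB7C went from 6.79 ± 1.78 to 36.9 ± 11.9 CPM (n = 3 each, edgeR adjusted p = 3.30e-05). RMDN2, opposite RMDN2-AS1, went from 8.33 ± 4.74 to 37.2 ± 1.55 CPM and NEK7 from 9.43 ± 0.593 to 37.5 ± 10.5 CPM. Without control library 3, the value was 3.61 for KCND2 and 3.72 for TNFRSF17. Only these 3 genes, ZBTB7C, RMDN2 and NEK7, stayed past the threshold in all 6 fits that left out a library. Without SOX9 sgRNA library 1 the calls of CDR1 (1.58) and MFSD13A (1.45) were lost, as were those of KCND2 (2.61), SLPI (2.07), TNFRSF17 (1.99), ZFP41 (1.62), RRAGC (1.38) and ZNF81 (3.00). TINF2 was lost without SOX9 sgRNA library 3 (1.61). Leaving out control library 1 also ended the calls of KCND2 (2.33), SLPI (1.64), TNFRSF17 (1.96), ZFP41 (1.73) and RRAGC (1.59), control library 2 those of TNFRSF17 (1.93), RRAGC (1.68) and ZNF81 (2.77), SOX9 sgRNA library 2 those of ZFP41 (1.90), RRAGC (1.75) and ZNF81 (3.01), and SOX9 sgRNA library 3 those of SLPI (1.93) and ZNF81 (2.89).

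Opposite counts, which leave out genes overlapping more than 1 gene on the other strand, were ranked at an average log2 CPM of at least 6. ENSG00000253348 (chromosome 5, 170174051 to 170215654, minus strand), opposite GABRP over 77 bp, fell from 812 ± 39.7 to 16.5 ± 8.02 CPM, a log2 fold change of -5.59 (SE 0.17, edgeR adjusted p = 6.26e-41). GABRP encodes the pi subunit of the GABA-A receptor, and its own counts fell by 2.93. MUC5B-AS1, opposite the gel-forming mucin gene MUC5B over 434 bp, fell by 4.82 (SE 0.30), and MUC5B's own counts fell by 1.95. C12orf60, opposite the matrix calcification inhibitor gene MGP over 76 bp, fell by 3.54 (SE 0.23). VIM-AS1 (chromosome 10, 17256238 to 17271984, minus strand), opposite VIM, which encodes the intermediate filament vimentin, fell from 6591 ± 209 to 2384 ± 117 CPM (log2 fold change -1.47, SE 0.059, edgeR adjusted p = 8.20e-33). VIM's own counts fell by 1.61. Further falls lay opposite TMEM139 (-2.16), the matrix glycoprotein gene THBS1 (-1.83), SERTAD4 (-1.69), DDIT4 (-1.58), CCN2 (-1.52), BMP6 (-1.39), KRT23 (-1.37) and DEPTOR (-1.36). DDIT4 and DEPTOR encode inhibitors of mTOR signalling. The count opposite BMP6 is that named for the protein-coding gene TXNDC5. TMEM139's own counts gave 0.07 (edgeR adjusted p = 0.94), apart from the count opposite it.

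**Figure D2:**
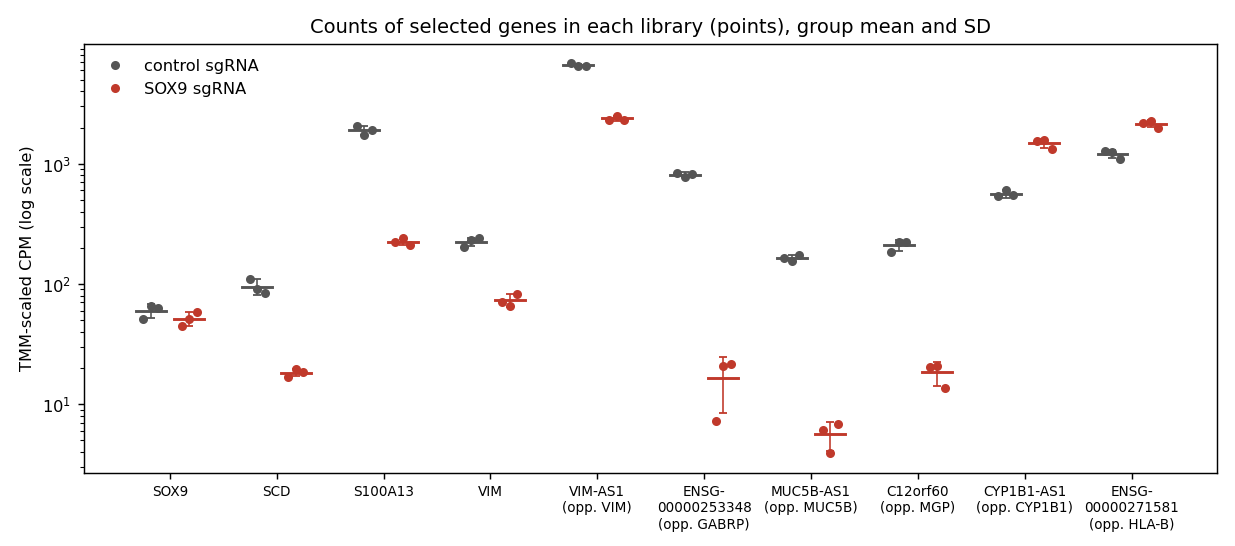
TMM-scaled CPM on a log axis for 10 genes, with each library as a point, the group mean as a line and the SD as a bar (n = 3 control in grey, n = 3 SOX9 sgRNA in red). SOX9 overlaps between groups at 60.01 and 51.2, whereas the count opposite GABRP falls from 812 to 16.5 and that opposite CYP1B1 rises from 563 to 1479.

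The largest rises of opposite counts at that depth lay opposite CYP1B1, which encodes an estrogen-metabolising cytochrome P450 (1.39, from 563 ± 40.8 to 1479 ± 135 CPM, edgeR adjusted p = 1.06e-22), IGFBP5 (1.04), LRIG1, an inhibitor of ERBB receptors (1.02), the heat shock gene HSPA1A (0.99), RIPK4 (0.97), NEURL1B (0.92), NQO1 (0.84), PTPRG (0.84), HLA-B (0.84), ZNF862 (0.82), PMM1 (0.76) and TRPC4AP (0.76). The own counts of ZNF862 (-0.29, edgeR adjusted p = 0.63) and TRPC4AP (-0.29, edgeR adjusted p = 0.68) had the other sign and were not past the threshold. The counts opposite LRIG1, HSPA1A, PMM1 and TRPC4AP are those named for the protein-coding genes SLC25A26, HSPA1L, CSDC2 and MYH7B. Among 2672 opposite counts, 103 were higher and 247 lower, 34 and 52 at 2-fold or more. With library totals alone, 282 were higher and 126 lower. All 12 named falls and 8 of the 12 named rises kept their call in every fit that left out a library. The count opposite NEURL1B was lost without control library 1 (0.69), that opposite NQO1 without control library 3 (0.69), and that opposite TRPC4AP without control library 3 (0.66) or SOX9 sgRNA library 3 (0.63). That opposite PMM1 was lost without control library 1 (0.62) or 2 (0.76) and without SOX9 sgRNA library 1 (0.67) or 3 (0.75).

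The cholesterol synthesis list, which also holds SCD, was called lower. Of 13 tested, 5 were lower and 0 higher, with 6 lower when adjusted over the list alone. The median log2 fold change was -0.63 and camera's adjusted p was 0.0047. Whether counts named for these genes measure their mRNAs is open. The adjusted p = 0.45 with an estimated correlation, and with the stricter filter 5 genes were tested and the adjusted p was 0.15. Besides SCD, the squalene epoxidase gene SQLE fell by 1.62 (SE 0.38) and the mevalonate kinase gene MVK, which lies opposite MMAB, by 0.78 (SE 0.16). DHCR7, outside the naming rule and chosen after its values were seen, fell by 1.78 (SE 0.59). Opposite counts gave a fall for 4 of 6 members, including the counts opposite ACAT2 (-0.80) and HMGCS1 (-0.56), with 4 lower adjusted over the list alone. For these the camera adjusted p was 2.88e-06, and the adjusted p = 0.055 with an estimated correlation. The count opposite ACAT2 is that named for TCP1.

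Ribosomal protein genes were the other list called lower. Their median was 65.1 raw CPM and 1 of 62 was among the 100 highest genes. Whether these counts measure ribosomal protein mRNA is therefore open. Of 60 tested, 6 were lower and 0 higher (6 adjusted over the list alone), with a median of -0.26 and a camera adjusted p of 0.012. The adjusted p = 0.45 with an estimated correlation, and it was 0.15 with the stricter filter, which left 33 genes, and 0.060 with fry. RPL14 fell by 0.58 (SE 0.11), RPL13 by 0.38 (SE 0.11) and RPL32, opposite CAND2, by 0.27 (SE 0.067). Under library totals RPL13 (-0.20) and RPL32 (-0.09) lost their calls with no change of sign. RPL13 also lost it without control library 1 (-0.33) or SOX9 sgRNA library 3 (-0.24), and RPL32 without control library 3 (-0.21). Opposite counts of 10 members had 2 lower, those opposite RPS23 (-0.30) and RPS3A (-0.31), with a camera adjusted p of 0.13. These 2 counts are named for ATG10 and SH3D19.

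**Figure D3:**
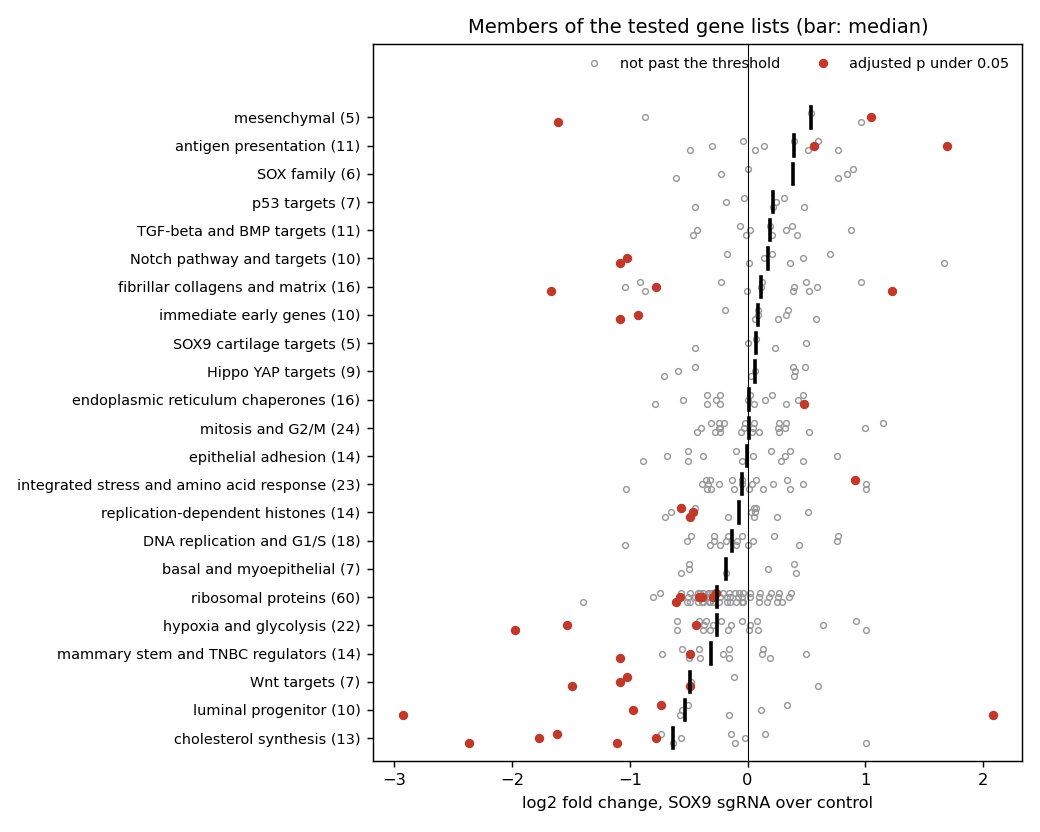
Log2 fold changes of SOX9 sgRNA over control (horizontal) for the tested members of 23 gene lists, with the number of tested members in brackets, members past the threshold in red, others open and the list median as a bar. Cholesterol synthesis has the lowest median at -0.63 and the mesenchymal list the highest at 0.54, the latter with VIM lower and S100A4 higher.

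Several cell-state lists held changed genes, with a call for the list only under other settings or not at all. In the luminal progenitor list, 3 of 10 tested genes were lower and 1 higher (4 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 0.24, and 0.0098, lower, with no filter on low counts, but 0.49 with an estimated correlation). KRT19 fell by 0.74 (SE 0.13) and KRT7, opposite KRT7-AS, by 0.97 (SE 0.29), both keratin genes of simple epithelia, beside GABRP, while SLPI rose. In the Wnt target list, 4 of 7 were lower and 0 higher (4 lower and 1 higher adjusted over the list alone, median -0.49, camera adjusted p = 0.057): MYC by 1.08 (SE 0.23), the Wnt antagonist gene SFRP1 by 1.49 (SE 0.38), the cell cycle gene CCND1, opposite LTO1, by 1.03 (SE 0.29) and CD44, opposite CD44-AS1, by 0.49 (SE 0.13). The Wnt list was called lower with library totals (adjusted p = 0.039), protein-coding genes alone (0.019), the replicate block (0.049), background subtraction (0.029) and fry (0.0013), and without control library 2 (0.040) or SOX9 sgRNA library 2 (0.045). With an estimated correlation the adjusted p was 0.45. The mesenchymal list moved both ways, with VIM lower and S100A4 higher by 1.05 (SE 0.17) among 5 tested (2 lower and 2 higher adjusted over the list alone, median 0.54, mean 0.01, camera direction down, adjusted p = 0.99). In the mammary stem cell and triple-negative regulator list, 2 of 14, MYC and CD44, were lower (2 adjusted over the list alone, adjusted p = 0.49). MYC and CCND1 were also the 2 lower genes of 10 in the Notch list (2 lower and 1 higher adjusted over the list alone, adjusted p = 0.99). KRT7 lost its call under library totals (-0.79), without control library 1 (-0.86) and without SOX9 sgRNA library 1 (-0.96) or 3 (-0.96). SLPI lost its call without control library 1 (1.64) and without SOX9 sgRNA library 1 (2.07) or 3 (1.93). CD44 lost its call under library totals (-0.31) and without control library 3 (-0.41), and CCND1 without SOX9 sgRNA library 2 (-0.97).

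Matrix, metabolic and stress lists followed with smaller numbers. Among 16 fibrillar collagen and matrix genes, THBS1, opposite ENSG00000259279, fell by 1.67 (SE 0.25) and COL18A1, opposite SLC19A1, by 0.78 (SE 0.23), while COL6A2 rose by 1.23 (SE 0.36) (3 lower and 2 higher adjusted over the list alone, median 0.12, mean -0.04, camera direction down, adjusted p = 0.99). In hypoxia and glycolysis, 3 of 22 were lower, namely DDIT4, opposite DDIT4-AS1, by 1.98 (SE 0.39), the hexokinase gene HK2, opposite HK2-DT, by 1.54 (SE 0.35) and ENO1, opposite ENO1-AS1, by 0.44 (SE 0.12) (4 adjusted over the list alone, adjusted p = 0.28, and 0.044 with fry but 0.49 with an estimated correlation). Of the immediate early genes, MYC and IER3 were lower among 10 (2 adjusted over the list alone, adjusted p = 0.96), IER3, opposite IER3-AS1, by 0.93 (SE 0.25). Among 14 replication-dependent histone genes, H3C12 fell by 0.49, H2AC11 by 0.57 and H2BC11 by 0.46 (3 adjusted over the list alone, adjusted p = 0.33). In antigen presentation, 2 of 11 were higher, HLA-F, opposite HLA-F-AS1, by 1.70 (SE 0.49), and the immunoproteasome gene PSMB10 by 0.57 (SE 0.18) (3 adjusted over the list alone, adjusted p = 0.24). CALR, opposite ENSG00000267458, rose by 0.48 (SE 0.12) as the only call among 16 endoplasmic reticulum chaperones (1 adjusted over the list alone, adjusted p = 0.96), and WARS1, opposite ENSG00000258666, by 0.91 (SE 0.30) among 23 genes of the integrated stress response (0 adjusted over the list alone, adjusted p = 0.96).

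Several calls in these matrix, metabolic and stress lists were lost when a library was left out. Without control library 1, the values of PSMB10 (0.57), WARS1 (0.68), COL18A1 (-0.72) and H2AC11 (-0.53) were no longer past the threshold, and the same held without control library 2 for PSMB10 (0.57) and HLA-F (1.32). Without control library 3 it held for PSMB10 (0.53), WARS1 (0.82), COL6A2 (1.08) and H2BC11 (-0.35). Without SOX9 sgRNA library 1 it held for PSMB10 (0.49), WARS1 (1.01) and COL6A2 (1.21). Without SOX9 sgRNA library 2 it held for HLA-F (0.96), WARS1 (0.73), COL6A2 (1.06), COL18A1 (-0.58), ENO1 (-0.32), IER3 (-0.76), H2AC11 (-0.47) and H2BC11 (-0.35), and without SOX9 sgRNA library 3 for PSMB10 (0.48), WARS1 (0.97) and COL18A1 (-0.66). Under library totals ENO1 (-0.25), COL18A1 (-0.59), H2AC11 (-0.39) and H2BC11 (-0.28) lost their calls with no change of sign.

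In counts named for the gene itself, no gene of the remaining lists passed the threshold. These were SOX9 cartilage targets (5 tested, adjusted p = 0.99), basal and myoepithelial (7, 0.99), epithelial adhesion (14, 0.99), Hippo YAP targets (9, 0.99), TGF-beta and BMP targets (11, 0.73), p53 targets (7, 0.96), DNA replication (18, 0.96), mitosis (24, 0.99) and the SOX family (6, 0.96), with camera's adjusted p in each case. Among cartilage targets CHADL had -0.45 (SE 0.21) and COL9A3 0.24 (SE 0.37). Whether counts named for these genes measure their mRNAs is open, so a lack of change in the lists is not shown. Some opposite counts of members did pass the threshold. Lower were those opposite CCN2 (-1.52), MDM2 (-0.43) and BIRC5 (-0.59), among others, and higher were those opposite ACTA2 (2.49) and JUNB (0.39), among others. Too few genes were tested for mature luminal (3), interferon response (3), NF-kB mediators (3), immune cell (4), endothelial and erythroid (1), and fibroblast and adipocyte markers (0 of 16), and 0 genes matched the mitochondrially encoded list. None of the markers of other cell types passed the threshold. Adjusted over the list alone, 1 gene was higher in the interferon list and 1 in the NF-kB list. No list was called higher, against 1 at an unadjusted camera p under 0.05, antigen presentation (0.044), which fry called higher (adjusted p = 0.012), while with an estimated correlation the adjusted p was 0.49.

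Read on opposite counts, 4 of 13 lists with enough genes were lower and 0 higher. Besides cholesterol synthesis these were hypoxia and glycolysis (camera adjusted p = 1.93e-05, adjusted p = 0.055 with an estimated correlation), fibrillar collagens and matrix (0.0015, adjusted p = 0.10 with an estimated correlation) and mitosis (0.0077, adjusted p = 0.11 with an estimated correlation). In hypoxia and glycolysis 2 of 8 were lower, opposite DDIT4 and opposite GAPDH (-0.59), with 4 lower and 1 higher adjusted over the list alone. In matrix 5 of 10 were lower, opposite THBS1, LOX (-1.92), LAMB1 (-1.59), COL4A2 (-1.03) and COL18A1 (-0.59), with 5 lower and 1 higher adjusted over the list alone. The counts opposite LOX and COL18A1 are those named for the protein-coding genes SRFBP1 and SLC19A1. The call opposite LAMB1 was lost without any single library, with values from -1.82 to -1.25, and LAMB1's own counts gave 0.39 (edgeR adjusted p = 0.46). In mitosis 1 of 9 was lower, opposite the survivin gene BIRC5 (-0.59), with 2 adjusted over the list alone. Among lists with no call, rises included the counts opposite ACTA2 (2.49) and OVOL1 (1.29) and falls those opposite ITGA6 (-1.05), CDH3 (-0.52) and VLDLR (-0.86). Adjusted p ranged from 0.13 to 0.81 over the 9 other lists. For all 13 lists camera compared the members with all tested genes and not with the other opposite counts alone.

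**Figure D4:**
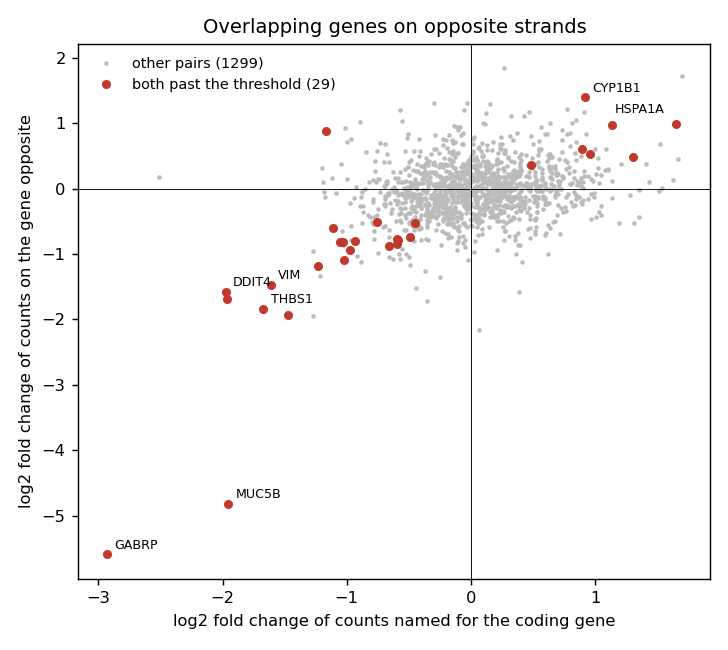
Log2 fold change of counts named for a protein-coding gene (horizontal) against that of the gene opposite it (vertical) for 1328 overlapping pairs, SOX9 sgRNA over control. The 29 pairs with both members past the threshold are in red, and 28 of them, including GABRP, VIM and CYP1B1, lie in the quadrants where both change the same way.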

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

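The counts of calls moved with several settings, and those on opposite counts, on genes without an exon opposite and after background subtraction were chosen after seeing the data. Library totals gave 625 higher and 249 lower genes and 282 and 126 opposite counts, through the shift of the median to 0.19. Testing against 1.5-fold left 20 higher and 73 lower genes and 12 and 34 opposite counts. Protein-coding genes alone gave 121 and 245, and 36 and 96 opposite counts. Genes without an exon opposite gave 40 and 68. These 2 settings test fewer genes. Among genes without an exon opposite, the main fit called 68 higher and 86 lower. Calls were thus also lost within that class, and the cause was not tested. DESeq2 called 130 genes and 65 opposite counts higher, and no filter 151 genes higher, and for these the cause was not tested. Other settings stayed within 1.5 times. For gene lists, fry called 1 higher and 3 lower, namely Wnt targets (adjusted p = 0.0013), cholesterol synthesis (0.016) and hypoxia and glycolysis (0.044), but not ribosomal proteins (0.060). Wnt targets were also called lower with library totals (0.039), protein-coding genes alone (0.019) and background subtraction (0.029), and the luminal progenitor list with no filter (0.0098). Lists lower were 0 with the stricter filter, 0 with an estimated correlation and 4 on opposite counts. Leaving out a library, which leaves fewer samples, gave 161 to 207 higher and 364 to 430 lower genes, 75 to 92 and 198 to 218 opposite counts, 0 lists higher and 2 to 3 lower, the added list being Wnt targets without control library 2 (adjusted p = 0.040) or SOX9 sgRNA library 2 (adjusted p = 0.045). SOX9 ranged from -0.34 to -0.14 in these fits and passed no threshold in any setting that gave a value. The stricter filter gave none.

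No gene among the 76 followed reversed its direction. All 76 kept their call with median-of-ratios or upper-quartile factors, 66 with library totals, 66 with DESeq2, 68 with limma-voom and 31 against 1.5-fold. Depth was low in both directions: 11 of the 12 largest rises had under 20 control counts, and 7 of the 12 largest falls under 20 SOX9 sgRNA counts.

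The replicate numbers showed little pairing of the libraries. Deviations from the group mean correlated at -0.0032, 0.019 and -0.011 between libraries of the same number, and control libraries 1, 2 and 3 went best with SOX9 sgRNA libraries 2, 2 and 1, the same number for 1 of the 3. With the replicate block, 175 genes were higher and 399 lower, and Wnt targets were called lower (adjusted p = 0.049), though not with an estimated correlation and no block (0.45).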

Other observations

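The genes and tests in the next paragraphs on the SOX9 locus, S100A1 and small RNAs were chosen after their values were seen, and so were the tests of strand shares, of ribosomal protein places, of pairs that change the same way and of other splits of the libraries. Around SOX9, the counts of genes not annotated as protein-coding passed the threshold while those of SOX9 did not. For ENSG00000267893 no biotype was found. Within 500 kb of SOX9, 5 genes were tested and 4 passed the threshold. LINC01152 (chromosome 17, 70026432 to 70034889, plus strand) fell from 169 ± 14.4 to 8.30 ± 3.00 CPM (log2 fold change -4.37, SE 0.28, edgeR adjusted p = 3.83e-21, n = 3 each). ENSG00000267893 (70036164 to 70036872, plus strand), opposite SOX9-AS1 over 152 bp, fell from 235 ± 21.3 to 8.74 ± 4.11 CPM (-4.72, SE 0.25). LINC02097 (70068474 to 70089622), also opposite SOX9-AS1, rose from 37.6 ± 11.2 to 75.2 ± 24.2 CPM (1.01, SE 0.28, edgeR adjusted p = 0.0093). These 3 lie upstream of SOX9. Downstream of it, ENSG00000263680 (70422080 to 70424993, plus strand), opposite LINC00511, fell by 1.22 (SE 0.19).

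At the S100A1 locus, ENSG00000272030, opposite S100A1 over 318 bp, fell from 2096 ± 148 to 441 ± 45.3 CPM (log2 fold change -2.25, SE 0.082), and S100A1's own counts fell by 1.93 (SE 0.18). ENSG00000272030 overlaps the span of S100A13 on the same strand. Whether its fall and that of S100A13 rest on the same fragments was not tested. ENSG00000227407, opposite the chloride channel gene TTYH1 over 120 bp, fell from 1172 ± 50.9 to 49.7 ± 5.54 CPM (-4.55, SE 0.12). ENSG00000272030 and ENSG00000227407 each overlap a second gene on the other strand and are therefore not among the opposite counts. ENSG00000267650, opposite the collagen gene COL5A3, rose from 6.37 ± 2.42 to 92.0 ± 7.99 CPM (3.84, SE 0.36). Among non-coding RNAs, 7SK, which holds the elongation factor P-TEFb inactive, fell from 23205 ± 1662 to 13549 ± 769 CPM (-0.78, SE 0.048), and the small nucleolar RNA SNORD3A fell by 1.09 (SE 0.19). MALAT1, a nuclear long non-coding RNA, rose by 0.69 (SE 0.14), with ENSG00000270117 on its other strand.

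Counts lay mainly on genes opposite abundant genes. In 1982 pairs of a protein-coding gene and a gene annotated as antisense, with at least 10 raw CPM together, the antisense member held more counts in 71.6% (Wilson 95% interval 69.6 to 73.6, over pairs, which are not independent). Abundant antisense transcripts counted on the right strand would leave ribosomal protein mRNAs, abundant in any growing cell, near the top, but 1 of 62 such genes was among the 100 highest. Their median was 65.1 raw CPM, and the 40 of them with no exon opposite also had a median of 65.1. Of the 100 highest genes, 1 was protein-coding with no exon opposite. These values argue against abundant antisense transcripts counted on the right strand. A candidate explanation is therefore counting with the strand setting opposite to the one this stranded kit needs, so that counts named for a gene hold mostly transcripts of the other strand. The reads, which would settle this, were not analysed here. Abundant antisense transcripts were the only biological explanation tested.

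A gene and the gene opposite it tended to change together. Over 1328 overlapping pairs the fold changes correlated across genes at r = 0.32 (bootstrap 95% interval 0.23 to 0.41; Spearman's rho 0.22; permutation p = 1e-05 for both, the smallest that 100000 permutations can give), and genes are not independent replicates. Neighbours on opposite strands within 10 kb and without overlap gave r = 0.064 (-0.0083 to 0.14, permutation p = 0.041) over 1006 pairs. Their interval lies below that of the overlapping pairs. The neighbours were not matched to those pairs in counts, on which the noise of fold changes, and so r, depends. Whether co-regulation of neighbours makes up the relation is therefore not settled by this difference. Of 29 pairs with both members past the threshold, 28 (96.6%, exact 95% interval 82.2 to 99.9) changed the same way, where their directions alone give 61.6%, and EPHX1 with TMEM63A was the exception. This is consistent with reads of a single transcript being counted partly on each strand, and shared regulation of overlapping genes stays open as a biological explanation.

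SOX9 sgRNA libraries detected more genes, and genes of low counts shifted up. After thinning all libraries to 776125 counts, SOX9 sgRNA libraries still detected 1740 more genes on average. With the 100 most abundant genes left out and thinning to 498024 counts, they detected 1483 more. The groups did not overlap either time. Library depth therefore does not account for the difference in detected genes. A smaller share of the 100 most abundant genes does not account for all of it. How much it accounts for cannot be read from these values, which were taken at unlike totals. A wider shift of shares was not tested. Counts over 362 olfactory receptor genes, silent in most tissues, were 0.206 ± 0.040 against 0.097 ± 0.015 raw CPM per kb (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow), from 28 to 85 counts per library. Subtracting that rate lowered the gap between the median log2 fold changes of genes in the lowest and highest quartile of expression from 0.168 to 0.131 (bootstrap SE 0.022). Counts were rounded after subtraction, which left those of short genes unchanged. The lowest quartile held 1990 genes before and 1740 after. How much of the gap comes from background in proportion to exon length therefore cannot be read from these values. A background of another shape or an effect of the SOX9 guide also stays open.

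The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 717 genes past the threshold, 238 higher and 479 lower, 350 opposite counts and 2 lists. In each case 1 of the 10 splits, the real one, gave as many, and the highest among the others was 0 genes, 0 opposite counts and 1 list.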
